A study of Mus musculus with 24 samples.

How the data were processed

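RNA was isolated with Trizol from mouse testis, and total RNA of each sample was amplified into biotin-labelled complementary RNA with the Illumina TotalPrep-96 kit, per the labels' protocols. Each of the 24 samples was read on 1 array of an Illumina mouse expression beadchip with 1 colour. The samples form 4 groups of 6 arrays: wild-type (WT) and NSun2 knock-out (KO) testes at 15 days and at 49 days, with replicates named A to F in each group. The labels give an F1 cross of CBA and C57BL/6J as the strain of every sample. The knock-out animals came from 2 lines, one made from a gene-trap embryonic stem cell line and one carrying an Nsun2tm1a allele, and the labels do not say which line a sample came from. The labels do not state that each array is a separate animal, so a p-value measures the spread between these samples. The arrays lie on 4 slides of 6, and each slide holds all 4 groups, with 1 or 2 arrays of each.

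The table used as the starting point holds the bead summary intensity of 45278 probes and 956 control rows per array, on a linear scale and not normalized, as deposited by the authors. Its detection p columns hold no values. The scanner software, the summary step and the array build are not given in the sources used here. A second table holds the authors' processed log2 values. Taking log2 of the intensities and quantile normalizing all 46234 rows gave the authors' log2 values to within 3.62e-05 on every array, so no background subtraction or centring is in them, and they served as an alternative. Gene names came from a platform annotation table and were updated through gene identifiers with a table of the GRCm38.p6 assembly. Of the probes, 34885 had 1 gene symbol, 18 had several and 10375 are unnamed here, and 34807 symbols were updated or kept through the identifier. No coordinates were used, and the assembly table served for names and for the order of neighbouring genes.

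Intensities were background-corrected by the normexp method with an offset of 16 and quantile normalized on the log2 scale (neqc) with limma 3.58.1 in R 4.3.3. The background was estimated from 946 dim control rows, whose median intensities lay below 400. The other 10 control rows had medians from 757.1 to 44453 and were left out of the fits. These rows carry no names in the table, so their use as background rests on their low level. The planned filter needed detection p-values; without them, the fallback fixed in advance kept the share of 0.5 of the probes with the highest mean log2 intensity, which is 22639 of 45278. For descriptions of single genes, a probe counted as above background on an array when fewer than 1% of the dim control rows (p under 0.01) were brighter. Between 16267 and 19051 probes per array passed that limit. The median probe intensity per array ran from 223.9 to 278.7 and the median of the dim control rows from 188.8 to 240.1. The number of arrays, 6 per group, limits the precision. Where a gene was above background on none of the arrays of a group, its fold is given as a lower bound, computed against the lowest level above background on each array. Where a gene was above background on some arrays of a group only, the fitted log2 change is given and its size depends on the offset.

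One linear model with a mean for each of the 4 groups was fitted to all 24 arrays with limma (lmFit and eBayes, 20 residual degrees of freedom), and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05, two-sided. Contrasts were KO against WT at 15 days, KO against WT at 49 days, their difference, and 49 against 15 days in WT and in KO. Log2 changes are on the background-corrected quantile-normalized scale with the offset, which understates the change of dim probes. Gene-level results use the brightest tested probe of each of 12166 genes. Genes named in the text follow a rule written before the data were examined: Nsun2, the 10 largest rises and 10 largest falls at each age among genes with adjusted p under 0.05, the 5 largest of each for the age effect in WT and for the difference, and up to 3 passing members per direction from each gene list, or the 2 largest values where none passed. Unnamed gene models were passed over.

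A set of 19 gene lists was written before the data were examined from general knowledge of the testis: Sertoli cell, Leydig cell, peritubular myoid and smooth muscle, macrophage and leukocyte, endothelial, red blood cell, epididymis, undifferentiated spermatogonia, differentiating spermatogonia, early meiotic prophase, pachytene and late meiosis, round spermatid, elongating spermatid, chromatoid body and piRNA pathway, RNA cytosine-5 methylation without Nsun2, integrated stress response, p53 targets, cholesterol synthesis, and cell division. Of their 284 entries, 263 were named on the array and 225 were tested; Piwil1 is in 2 of the lists. Each list was tested with camera at a preset correlation of 0.01 in 3 contrasts, 57 tests in 1 Benjamini-Hochberg family. At the preset correlation 11 of the 57 tests passed. With an estimated correlation 0 passed, at a lowest adjusted p of 0.913, and the rotation test fry, which asks whether a list's genes move on balance in 1 direction and compares them with no other genes, passed 21 of the 57.

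Alternatives were no background correction, scale and cyclic loess normalization, quantile normalization within each age, the authors' log2 values, other filters on dim probes, the slide as a fixed and as a random block, values within each slide, the replicate letter as a block, array weights, fits to the 12 arrays of 1 age, a trended robust variance, 1 probe per gene, a minimum fold of 1.5, and leaving out each array in turn. Added after seeing the data were a filter on probes above background on at least 6 arrays, a fit without KO 15-day replicate B and WT 15-day replicate A, weights estimated per group, and the overlap of the ages taken from fits to the 12 arrays of each age.

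The scripts were tested on simulated data with the measured group means and the measured spread of each probe in each group. The spread was unequal: the median SD over probes was 0.54 for the KO arrays at 49 days, and 0.19 to 0.24 for the other groups, while the fit to 24 arrays uses a pooled value. With 200 of 22639 probes changed at 15 days, that fit recovered 7.46% of changes of 0.5 log2, 59.7% of changes of 1 and 98.5% of changes of 2, and 8.33% of its 120 calls were false. With 200 probes changed at 49 days it recovered 17.9%, 77.6% and 92.4%, and 223 of its 348 calls (64.1%) were false, against 25.2% in a fit to the 12 arrays of that age. With 11319 probes given the measured 49-day difference and 11320 left unchanged, false calls were 8.39% of the calls of the fit to 24 arrays and 3.85% in the fit to 12. The 49-day counts of the fit to 24 arrays are therefore too high by some margin, and the count from the 12 arrays is printed beside them. Camera called 0 of 100 unchanged simulated lists, but the simulated genes varied independently of each other, so this does not show how the test behaves at the estimated correlations of the lists (0.0520 to 0.887).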

Results

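Testes of mice lacking NSun2, an enzyme that methylates carbon 5 of cytosine in RNA, were compared with wild-type (WT) testes at 15 and at 49 days. In mouse testis the first wave of germ cells is passing through meiosis at 15 days, and by 49 days the tissue also holds round and elongating spermatids. The comparison asks which transcripts depend on NSun2 at each age, and the study's title places the protein in the chromatoid body, a granule of germ cells rich in RNA and in proteins of the piRNA pathway. Expression was measured on 24 arrays, 6 for each of WT and knock-out (KO) at 15 days and WT and KO at 49 days. Between 16267 and 19051 probes were above background on an array, and 22639 probes, which represent 12166 named genes, entered the tests. The first principal component held 83.1% of the variance and the second 6.75%. WT arrays lay between -122.8 and -96.4 on the first component at 15 days and between 190.4 and 203.1 at 49 days. KO arrays lay between -145.4 and -126.1 at 15 days and spread from -68.4 to 153.5 at 49 days.

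The targeted gene was lower in KO at both ages. The 1 probe for Nsun2 fell by 1.47 on the log2 scale at 15 days (SE 0.21, limma adjusted p = 3.06e-04) and by 1.15 at 49 days (SE 0.21, limma adjusted p = 5.44e-05). Its level was above background on 0 of 6 KO arrays at either age, on 5 of 6 WT arrays at 15 days and on 3 of 6 at 49 days, so the fold is bounded at at least 1.16-fold lower at 15 days and at least 1.17-fold lower at 49 days. At 15 days the KO arrays (4.91 to 5.29) and the WT arrays (5.85 to 7.24) did not overlap. At 49 days WT replicate B (5.79) lay below KO replicate C (6.07), and neither was above background. Within the 4 slides KO minus WT was -1.53, -2.19, -1.46 and -1.21 at 15 days and -1.18, -0.27, -1.31 and -1.85 at 49 days, and with the slide as a block it was -1.53 and -1.09. The sources used here do not place the probe relative to the inserted cassettes, so its level checks the labels only in part.

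**Figure D1:**
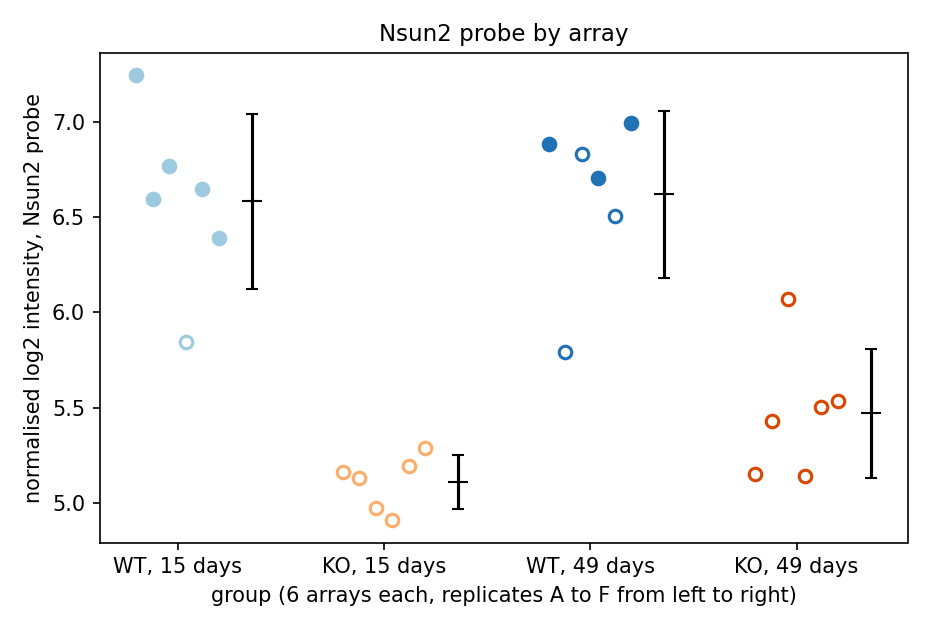
Normalised log2 intensity of the Nsun2 probe (vertical axis) on each array, by group (horizontal axis, replicates A to F from left to right); filled points are above background, open points are not, and bars give the mean and SD of 6 arrays. The 15-day KO arrays sit between 4.91 and 5.29, below each of the WT arrays of that age.

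At 15 days, 8 of 18 genes of the pachytene list, which marks late spermatocytes, were lower in KO testes. Ldhc, the testis form of lactate dehydrogenase, fell by 4.47 on the log2 scale (SE 0.62, limma adjusted p = 2.64e-04; above background on 5 of 6 KO arrays), and Piwil1, which binds piRNAs in spermatocytes and round spermatids, fell by 3.96 (SE 0.46, limma adjusted p = 3.85e-05). Fabp9, a fatty-acid binding protein of male germ cells, fell by 3.99 (SE 0.56), and the acrosomal protein gene Dkkl1 fell by 3.42 (SE 0.54). The other large falls were Clec2m (-3.57), the outer dense fibre gene Odf4 (-3.40), Lypd10 (-3.38), Mdh1b (-3.36), the tektin gene Tekt1 (-3.33) and Lypd11 (-3.16). The largest rises were smaller. Ctsl, the lysosomal protease cathepsin L, rose by 2.23 (SE 0.28, limma adjusted p = 1.07e-04), and Erap1, a peptide-trimming enzyme of the endoplasmic reticulum, rose by 2.01 (SE 0.39). Erap1 lies within 50 genes of Nsun2 on its chromosome and Ctsl within the next 100, and Erap1 stood at 7.15 on WT replicate A and between 4.90 and 5.07 on the other 5 WT arrays. Sel1l3 (1.74), the macrophage receptor gene Vsig4 (1.73), the oestradiol-forming enzyme gene Hsd17b1 (1.47), the matrix protein gene Dpt (1.42), the lysozyme gene Lyz2 (1.40), the angiotensin receptor gene Agtr1a (1.36) and Gpx8 (1.24) rose too, and Wfdc17, not above background in WT, was at least 1.51-fold higher. The second probe for Lyz2 and 1 of 2 further probes for Odf4 did not give the same call.

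Across the array, 948 of 22639 probes changed at 15 days, 248 higher and 700 lower in KO, and they mark 571 genes, 134 higher and 437 lower. The number of calls depended on which arrays set the spread. A fit to the 12 arrays of this age called 3849 probes (1759 higher, 2090 lower), and leaving out KO 49-day replicate D, an array outside the comparison, gave 2386. Leaving out a single array of the comparison gave as few as 468 (without KO 15-day replicate D), with 536, 595 and 513 without WT 15-day replicates A, B and C. With the slide as a fixed block there were 1281 calls and as a random block 793. The balance of directions depended on the scaling: 26.2% of the calls were higher in KO after quantile normalization and 49.2% (358 higher, 369 lower) after scale normalization, against 38.5% without background correction and 37.6% on the authors' log2 values.

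The pachytene and late meiosis list held 18 measured genes, of which 8 fell, 0 rose and 10 did not pass. Adjusted over the list alone 10 fell and 1 rose. Its mean change was -1.42 (camera adjusted p = 3.44e-08; adjusted p = 0.913 with an estimated correlation). Besides Ldhc and Piwil1, Spink2, a protease inhibitor of sperm, fell by 2.33. In the list of the chromatoid body and piRNA pathway, 3 of 20 measured genes fell and 17 did not pass, and 8 fell when adjusted over the list alone, with a mean of -0.85 (camera adjusted p = 2.30e-06; adjusted p = 0.913 with an estimated correlation). They were Piwil1 and the Tudor-domain genes Tdrd6 (-2.69) and Tdrd5 (-1.77). Piwil1 is also in the pachytene list, which was lower on the same arrays. A change of the pathway was therefore not told apart from fewer late spermatocytes. In early meiotic prophase, Msh4 (-1.74) and Spo11 (-1.47), which act in meiotic recombination, fell and 13 of 15 measured genes did not pass. Adjusted over the list alone 5 fell, and the list mean was -0.86 (camera adjusted p = 2.11e-04, and 0.913 with an estimated correlation). Fry did not pass this list (adjusted p = 0.103). Within the 4 slides the pachytene mean was -2.11, -1.04, -1.48 and -1.69, the chromatoid body mean -1.06, -0.70, -0.78 and -1.12, and the early meiotic mean -0.85, -0.46, -0.94 and -1.54. With the slide as a block they were -1.52, -0.91 and -0.97.

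The spermatid lists could show little at 15 days, since 13 of 23 round and 10 of 17 elongating spermatid genes were above background on none of the WT arrays of that age. In the round spermatid list Dkkl1 fell and 22 of 23 measured genes did not pass (3 fell when adjusted over the list alone; mean -0.40, camera adjusted p = 0.154). None of the 17 measured genes of the elongating spermatid list passed, whether adjusted over all probes or over the list alone (mean 0.018, and -0.042 after cyclic loess; camera adjusted p = 0.935); its largest values were Odf2 at -1.25 (SE 0.41) and Akap3 at -0.78 (SE 0.47). On that list KO replicate B stood 1.59 above the WT mean and WT replicate A 0.81 above it, while the other 10 arrays of this age lay between -0.38 and -0.05. Without these arrays, a setting chosen after seeing the data, 403 probes were called. Spermatogonial lists showed little change. In undifferentiated spermatogonia the transcriptional regulator gene Id4 fell by 0.81, a call its second probe did not give, and 11 of 12 measured genes did not pass (1 fell over the list alone; mean -0.025, and 0.032 after scale normalization; camera adjusted p = 0.935). In differentiating spermatogonia 0 of 8 passed either way (mean 0.15, camera adjusted p = 0.375), with Sohlh2 at -0.53 (SE 0.30) and the receptor gene Kit at 0.41 (SE 0.24).

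Among the lists of other testis cells, the macrophage and leukocyte list passed on a single called gene and in 32 of 41 settings. Lyz2 rose and 11 of 12 measured genes did not pass (1 rose over the list alone), with a list mean of 0.55 (camera adjusted p = 0.0297; adjusted p = 0.913 with an estimated correlation). Within slides that mean was 0.18, 1.78, -0.38 and 1.47, and with the slide as a block 0.67. The call was lost without KO replicate D (mean 0.35, adjusted p = 0.203) or WT replicate A (0.36, adjusted p = 0.186). Fry did not pass this list either (adjusted p = 0.304). None of the measured genes passed, over all probes or over the list alone, in the Sertoli cell list (14 genes, mean 0.12, camera adjusted p = 0.384; Tsx -0.49, Amh 0.34), the Leydig cell list (9, mean 0.16, 0.541; Ces1d 0.64, Hsd17b3 0.59) or the peritubular myoid and smooth muscle list (7, mean 0.15, 0.391; Des 0.39, Mylk 0.33). The same held for the endothelial list (7, mean 0.12, 0.564; Emcn 0.36, Esam 0.36), red blood cells (3, mean -0.15 but median 0.03, 0.780; Alas2 -0.60, Hba-a1 0.13) and the epididymis list (2, mean 0.17, 0.553; Lcn8 0.32, Cst11 0.01, and -0.018 after cyclic loess).

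Pathway lists did not pass as sets at 15 days. Vldlr, a lipoprotein receptor gene, rose by 0.98 among 17 measured genes of the integrated stress response (1 over the list alone; mean 0.15, camera adjusted p = 0.351). Among 11 measured p53 targets Bbc3, which promotes apoptosis, rose by 0.84 and Mdm2, a negative regulator of p53, fell by 0.69 (2 rose and 1 fell over the list alone; mean 0.17, camera adjusted p = 0.391). For Vldlr and for Mdm2, 1 of 2 further probes did not give the same call. None of the 7 measured genes of RNA cytosine-5 methylation without Nsun2 passed over all probes and 1 fell over the list alone (mean -0.13, camera adjusted p = 0.391); Ybx1 stood at -0.48 (SE 0.15) and Nsun7 at -0.40 (SE 0.21). None of 10 cholesterol synthesis genes (mean 0.21, camera adjusted p = 0.172; Nsdhl 0.76, Msmo1 0.40) or 13 cell division genes (mean -0.029, and 0.011 after scale normalization, with the test pointing up, adjusted p = 0.935; Top2a -0.33, Mcm7 -0.29) passed either way. Of the 29 named genes that changed at 15 days, 28 had the same sign on all 4 slides, the exception being Erap1 at -0.29 on slide 2. Leaving out 1 array ended the call of 10 of them: at the highest adjusted p without KO replicate D for Spo11 (0.151), Lyz2 (0.125), Bbc3 (0.121), Msh4 (0.121), Id4 (0.102) and Hsd17b1 (0.0585), without WT replicate C for Dpt (0.0940), Spink2 (0.0641) and Vldlr (0.0536), and without WT replicate A for Vsig4 (0.112).

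**Figure D2:**
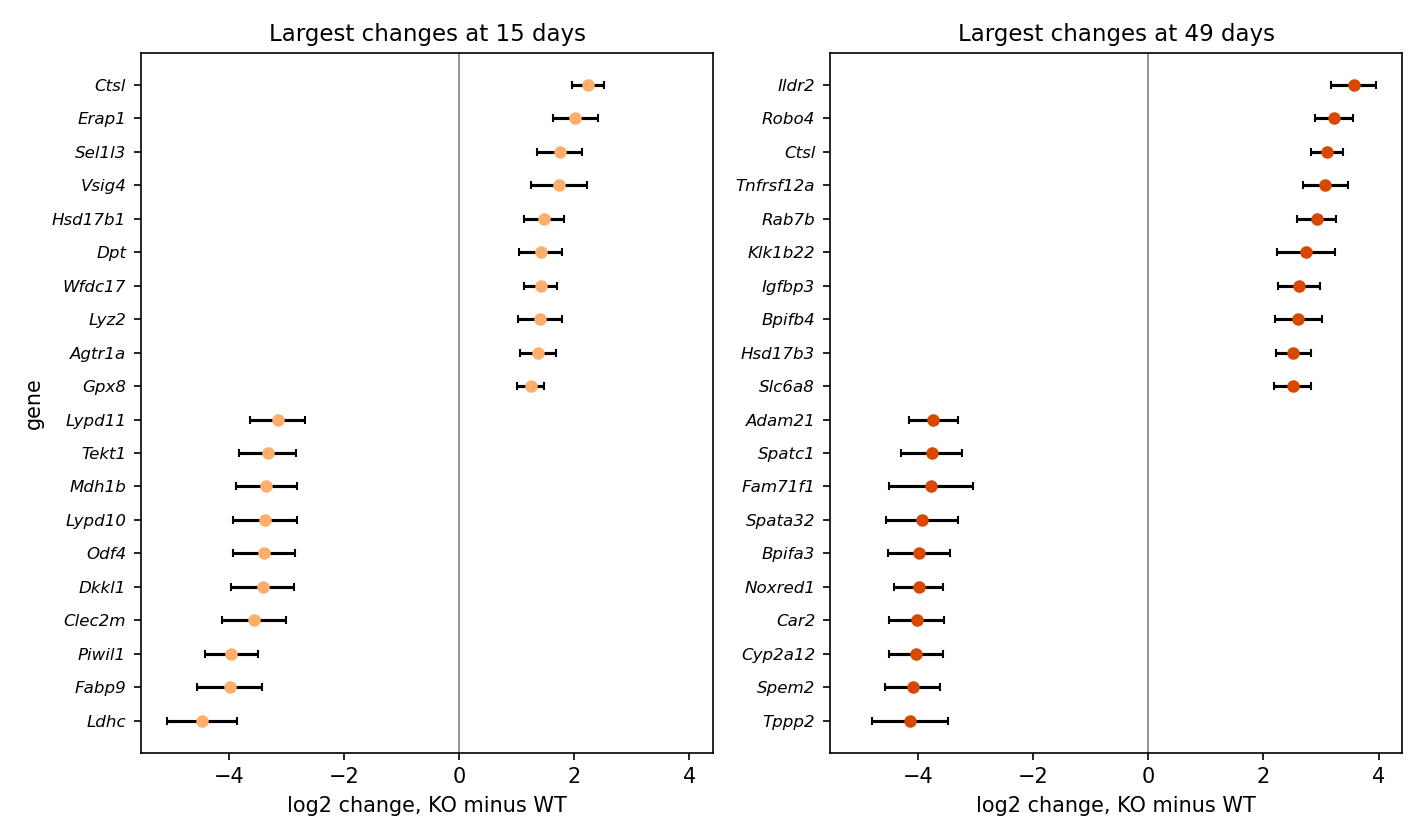
Log2 change of KO minus WT (horizontal axis, points with SE from the fit to 24 arrays) for the 10 genes with the largest rise and the 10 with the largest fall at 15 days (left) and at 49 days (right). Falls at 15 days run from -4.47 for Ldhc to -3.16 for Lypd11, and rises at 49 days reach 3.57 for Ildr2.

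At 49 days, transcripts of spermatids were lower in KO testes and transcripts of Sertoli cells, the somatic cells that nurse the germ cells, were higher. Tppp2, a tubulin-associated protein of sperm, fell by 4.15 on the log2 scale (SE 0.67, limma adjusted p = 1.53e-05), and Spem2 fell by 4.10 (SE 0.48, limma adjusted p = 6.31e-07). Cyp2a12 (-4.04), the carbonic anhydrase gene Car2 (-4.03), Noxred1 (-3.99), Bpifa3 (-3.98), Spata32 (-3.94), Fam71f1 (-3.79), Spatc1 (-3.77) and the ADAM-family gene Adam21 (-3.74) followed. Ildr2 rose by 3.57 (SE 0.40, limma adjusted p = 3.39e-07), Robo4, a receptor of endothelial cells, by 3.23 (SE 0.33; its other probe did not give the same call) and Ctsl by 3.11 (SE 0.28; WT replicate B stood at 6.83 and the other WT arrays between 4.99 and 5.46). Tnfrsf12a, the receptor of the cytokine TWEAK, and Igfbp3, which binds insulin-like growth factors, were not above background in WT and were at least 3.46-fold and at least 3.53-fold higher. Rab7b (2.92), the kallikrein gene Klk1b22 (2.73), Bpifb4 (2.60), the testosterone-forming enzyme gene Hsd17b3 (2.52) and the creatine transporter gene Slc6a8 (2.51) rose as well.

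In all, 15697 of 22639 probes changed at 49 days, 9464 higher and 6233 lower, and they mark 8907 genes, 5688 higher and 3219 lower. KO arrays of this age differed from one another more than the other groups did, and the fit to the 12 arrays of this age, which was less prone to false calls in the simulation, called 13946 probes. With the slide as a fixed block there were 15585 calls. Among probes above background on all 24 arrays 8573 changed, 70.8% of them higher. The balance turned with the normalization: 60.3% of calls were higher in KO after quantile normalization and 40.5% (6142 higher, 9008 lower) after cyclic loess, which moved the median change of the tested probes from 0.21 to -0.12.

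In the round spermatid list 23 of 23 measured genes fell, also when adjusted over the list alone, with a mean of -2.09 (camera adjusted p = 3.87e-08; adjusted p = 0.913 with an estimated correlation). Tssk6, a kinase of late spermatids, fell by 3.53, the sperm calcium channel gene Catsper1 by 2.99 and the fusion protein gene Izumo1 by 2.52. In the elongating spermatid list 15 of 17 fell, 16 over the list alone, with a mean of -2.41 (camera adjusted p = 2.27e-06; adjusted p = 0.913 with an estimated correlation), among them Spata3 (-3.47), Spata18 (-3.34) and the protamine-family gene Prm3 (-3.00). In pachytene and late meiosis 10 of 18 fell, 1 rose and 7 did not pass, the same numbers over the list alone. The mean was -0.99 (camera adjusted p = 0.00379, and 0.913 with an estimated correlation), and fry did not pass this list (adjusted p = 0.0550). The glycolytic gene Pgk2 (-2.12), the meiotic cyclin gene Ccna1 (-1.84) and Nme5 (-1.65) fell, and the cyclin gene Ccnb3 rose by 1.35. Early meiotic prophase did not pass as a set: Rec8, a meiotic cohesin, fell by 1.33 and Syce2, of the synaptonemal complex, by 1.22, and 13 of 15 did not pass (2 fell over the list alone; mean -0.52, camera adjusted p = 0.150). That mean leaned on KO replicate D, at -2.86, and within slides it ran from -1.63 to 0.19, below 0 on 2 of 4. Within slides the round spermatid mean was -1.90, -2.81, -1.42 and -2.53, the elongating mean -2.53, -3.35, -1.62 and -2.81, and the pachytene mean -0.60, -0.93, -0.56 and -1.66. With the slide as a block these were -2.10, -2.41 and -0.88.

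The 6 KO arrays of 49 days were not alike. Against the WT mean, the round spermatid score was -4.40 on replicate D and -0.43 on replicate F, and the elongating spermatid score ran from -4.50 to -0.33 on the same replicates, with an SD of 1.52 between KO arrays and 0.10 between WT arrays. In the round spermatid score replicate A (-0.57) lay near replicate F, while B, C and E stood at -1.87, -2.87 and -2.42. The labels do not say which of the 2 knock-out lines an array came from, so a link with the line was not tested. On replicate D the early meiotic (-2.86), pachytene (-3.23) and chromatoid body scores (-2.39) were low as well, while the early meiotic score of the other 5 KO arrays lay between -0.46 and 0.20. Without replicate D the pachytene mean at 49 days was -0.54 (adjusted p = 0.0242), and Syce2 was at -0.81. Leaving out any 1 array gave between 14802 and 16465 calls.

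Sertoli cell genes rose together. Of 14 measured genes 14 rose, also over the list alone, by a mean of 1.65 (camera adjusted p = 3.13e-04; adjusted p = 0.913 with an estimated correlation), and the list score was higher on 6 of 6 KO arrays, from 0.80 to 2.45 above the WT mean. Fshr, the receptor of follicle-stimulating hormone, rose by 2.23, and Inha, a subunit of inhibin, by 2.06. Gata1, a transcription factor not above background in WT, was at least 2.37-fold higher. Within slides the list mean was 1.62, 2.09, 1.61 and 1.64, and with the slide as a block 1.68. These rises were measured in the same arrays in which the spermatid lists were lower.

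Lists of other somatic cells held many genes that rose but did not pass as sets by camera. Fry, which compares a list with no other genes, passed the Leydig (adjusted p = 3.82e-04), macrophage (0.00167), peritubular (0.00167) and endothelial lists (0.0463). It did not pass red blood cells (0.0550) or the epididymis list (0.808). Across the array, 5688 of 12166 genes were called higher at this age. In the Leydig cell list 8 of 9 rose, also over the list alone (mean 1.28, camera adjusted p = 0.154), among them the steroidogenic genes Hsd17b3 and Cyp17a1 (1.54) and the carboxylesterase gene Ces1d (1.75). In macrophages and leukocytes 10 of 12 rose, also over the list alone (mean 1.42, camera adjusted p = 0.0848), with the antigen-presentation genes H2-Aa (1.88) and Cd74 (1.66) and the complement gene C1qa (1.65). In the peritubular and smooth muscle list 5 of 7 rose and 1 fell, the same over the list alone (mean 0.58, camera adjusted p = 0.391): Acta2 (1.62), Mylk (1.49) and Des (1.36) rose and the actin gene Actg2 fell by 2.21. In the endothelial list 4 of 7 rose, also over the list alone (mean 0.57, camera adjusted p = 0.564), among them Esam (1.21), Cdh5 (1.15) and Emcn (0.94). The globin genes Hba-a1 (1.12) and Hbb-bt (1.03) rose among 3 red blood cell genes (2 over the list alone; mean 0.66, camera adjusted p = 0.711). In the epididymis list 0 of 2 passed either way (mean 0.06, and -0.21 after cyclic loess, with the test pointing down, adjusted p = 0.935; Lcn8 0.25, Cst11 -0.14).

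The spermatogonial lists held genes that rose at 49 days but did not pass as sets by camera, where 5688 of all 12166 genes were called higher. By fry the undifferentiated (adjusted p = 0.00167) and differentiating lists (1.73e-04) passed. In differentiating spermatogonia 6 of 8 rose, also over the list alone (mean 1.03, camera adjusted p = 0.195), among them the cyclin gene Ccnd2 (1.79), Kit (1.55) and Stra8, which marks the entry into meiosis and was above background on 3 of 6 KO arrays and 0 of 6 WT arrays. In undifferentiated spermatogonia 7 of 12 rose, also over the list alone (mean 0.55, camera adjusted p = 0.422), with Foxo1 at 1.42, Sall4 at 0.73 and the receptor gene Ret at least 1.83-fold higher. In the chromatoid body and piRNA pathway list 9 of 20 fell and 3 rose, and over the list alone 8 fell and 3 rose (mean -0.58, camera adjusted p = 0.0976). The kinesin gene Kif17 (-2.54), the piRNA methyltransferase gene Henmt1 (-1.61) and Gtsf1 (-1.45) fell, and Dicer1 (0.93), Ago2 (0.58) and Piwil4, above background on 1 of 6 KO arrays and 0 of 6 WT arrays, rose.

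Apart from the p53 targets, the pathway lists at 49 days held changes in both directions. None of the lists below passed by camera. Fry passed the p53 targets (adjusted p = 8.23e-07), the integrated stress response (0.00167) and cholesterol synthesis (0.0158). It did not pass RNA cytosine-5 methylation (0.294) or cell division (0.519). Among all 12166 genes, 5688 were called higher and 3219 lower. For RNA cytosine-5 methylation without Nsun2, 2 of 7 rose and 2 fell, the same over the list alone (mean -0.08, camera adjusted p = 0.480): the ribosomal RNA methyltransferase gene Nsun5 (0.76) and the export factor gene Alyref (0.72) rose, and Nsun7 (-1.01) and Ybx1 (-0.65) fell. In the integrated stress response 13 of 17 rose and 3 fell, the same over the list alone (mean 0.59, camera adjusted p = 0.395). The amino-acid transporter genes Slc3a2 (1.52, above background on 2 of 6 WT arrays) and Slc7a11, above background on 5 of 6 KO arrays and 1 of 6 WT arrays, and the serine synthesis gene Psat1 (1.38) rose, while Chac1 (-1.54), Ddit3 (-0.70) and Asns (-0.58) fell. Of 11 p53 targets 7 rose, also over the list alone (mean 0.78, camera adjusted p = 0.195), among them Phlda3 (1.79), Sesn1 (1.46) and the death receptor gene Fas, at least 1.33-fold higher. In cholesterol synthesis 5 of 10 rose and 1 fell, the same over the list alone (mean 0.49, camera adjusted p = 0.697), with Msmo1 (1.73), Dhcr7 (1.14) and Insig1 (1.07) higher and Cyp51 lower (-1.25). In cell division 4 of 13 rose and 3 fell, the same over the list alone (mean 0.16, and -0.34 after cyclic loess, with the test pointing down, adjusted p = 0.935): the replication genes Mcm2 (1.35), Mcm4 (1.26) and Mcm5 (0.88) rose, and the mitotic genes Plk1 (-1.06), Birc5 (-0.85) and Aurkb (-0.52) fell, by 0.65, 0.41 and 0.32 without KO replicate D. Of 84 named genes that changed at 49 days, 82 had the same sign on all 4 slides, the exceptions being Sall4 (-0.28) and Mcm5 (-0.10) on slide 4, and 84 kept the call when any 1 array was left out, while 8 lost it after cyclic loess, 8 with weights per group (chosen after seeing the data) and 2 in the fit to 12 arrays. Further probes for Kit, Insig1, Fas, Sall4, Ybx1, Ago2, Nsun5, Hbb-bt and Sesn1 did not all give the same call.

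**Figure D3:**
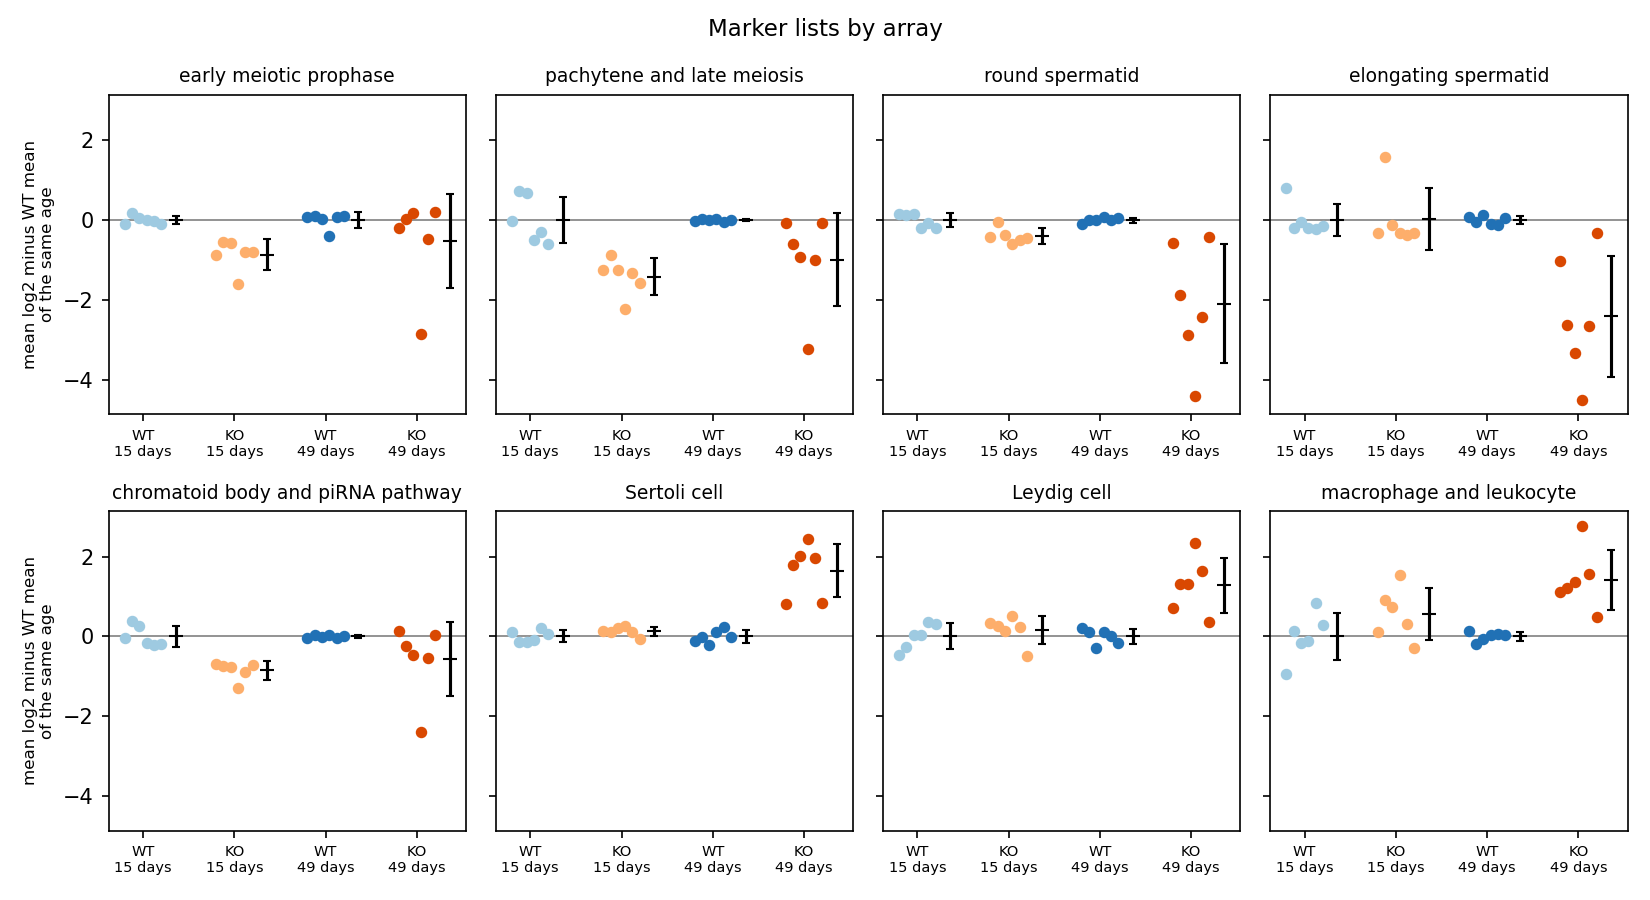
Mean log2 level of 8 gene lists on each array minus the WT mean of the same age (vertical axis), by group (horizontal axis, replicates A to F from left to right); bars give the mean and SD of 6 arrays. At 49 days the round spermatid score of the KO arrays runs from -4.40 to -0.43, and the Sertoli score from 0.80 to 2.45.

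By camera at the preset correlation, the KO effect differed between the ages for the lists of Sertoli cells and of round and elongating spermatids, each at an adjusted p = 0.913 with an estimated correlation. Among single genes Piwil1, which fell at 15 days, had a KO effect higher by 3.34 on the log2 scale at 49 days, and the interaction passed upward for Ldhc and Fabp9 as well. The KO effect on Piwil1 (-0.62), Ldhc (-0.64) and Fabp9 (-0.87) at 49 days did not pass. Ldhc and Fabp9 lie near the top of the scale there, with KO means of 15.26 and 14.95, so the size of their difference between ages is not measured. Kcnh3, a potassium channel gene, and the kallikrein gene Klk1b21 also differed upward (2.95 and 2.90). Car2 (-4.37), Pdzd8 (-4.15), Spem2 (-4.12), Noxred1 (-4.08) and Tppp2 (-4.07) differed downward; the second probe for Pdzd8 did not give the same call. The interaction passed for 11050 probes, 6922 of them (62.6%) with a higher effect at 49 days, and after cyclic loess the balance turned, with 3382 higher and 6138 lower (35.5% higher). For Nsun2 itself it was 0.32 (SE 0.29, limma adjusted p = 0.366). As lists, Sertoli cell genes differed by 1.53 (13 of 14 genes, also over the list alone; camera adjusted p = 4.14e-04), round spermatid genes by -1.70 (17 of 23 lower and 1 higher, the same over the list alone; camera adjusted p = 9.95e-07) and elongating spermatid genes by -2.43 (14 of 17 lower, 15 over the list alone; camera adjusted p = 9.16e-07). These 3 lists had an adjusted p = 0.913 with an estimated correlation. At 15 days most spermatid genes lie near background, so the spermatid differences follow largely from the 49-day effect. Among probes above background on all 24 arrays the round spermatid difference missed the threshold (adjusted p = 0.0684). The other 16 lists did not pass by camera, with adjusted p from 0.261 for Leydig cells to 0.935 for the chromatoid body list. Of these, fry passed the Leydig (adjusted p = 0.0158), undifferentiated (0.0158) and differentiating spermatogonia (0.0139) and p53 target lists (3.45e-04). In 6 of the 16 lists camera pointed down although the mean difference was above 0: early meiotic prophase (0.35), pachytene and late meiosis (0.43), chromatoid body (0.28), cholesterol synthesis (0.28), cell division (0.19) and RNA cytosine-5 methylation (0.06, median -0.16). After cyclic loess their means lay between -0.37 and -0.15. The median of all tested probes was 0.23.

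Genes called at both ages were counted over the 12166 genes, in comparisons that share no array. Of 437 genes lower at 15 days, 205 were also lower at 49 days, where 115.6 would be shared by independent lists (Fisher's exact test across genes, which are not independent, p = 9.64e-21), and 45 were higher, where 204.3 would be. Of 134 genes higher at 15 days, 69 were higher at 49 days against 62.6 for independent lists (same exact test, p = 0.296), and 19 were lower against 35.5 (p = 7.63e-04). Both calls use a spread pooled over 24 arrays, so genes with a low spread are likelier to be called at both ages. With each age fitted to its own 12 arrays, chosen after seeing the data, 525 of 1273 genes lower at 15 days were lower at 49 days, against 300.0 for independent lists, and 175 were higher against 534.4. Of 1059 genes higher at 15 days, 790 were then higher at 49 days against 444.5 (same exact test, p = 2.37e-112), and 79 were lower against 249.6, so the overlap of the rises depended on the fit.

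Age in WT gave the most calls of the 5 contrasts. The largest rises from 15 to 49 days were those of Cabs1, Gtsf1l and Smcp, which were not above background at 15 days and rose by at least 438-fold, 425-fold and 557-fold, and of Gsg1 and the histone variant gene H2al1e. The latter were above background on 1 of 6 arrays at 15 days and Gsg1 stood at 15.78, near the top of the scale, at 49 days, so the fitted rises of 10.36 and 10.02 are not exact sizes. On WT 15-day replicate A Gsg1 stood at 7.04 and on the other 5 between 4.94 and 5.35. The largest falls were Dlk1 (-5.47), the collagen genes Col1a1 (-5.13) and Col3a1 (-4.98), the elastin gene Eln (-4.62) and the microfibril gene Mfap2, at least 13.2-fold lower and not above background at 49 days. The test passed for 18413 probes in WT (6234 higher, 12179 lower with age) and for 13080 in KO (4886 higher, 8194 lower). After cyclic loess 55.9% of the WT calls rose with age, against 33.9% after quantile normalization, and 60.2% of the KO calls (7361 higher, 4872 lower), against 37.4%. The median of the tested probes moved from -0.54 to 0.11 in WT and from -0.21 to 0.099 in KO.

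The KO effect at 49 days ran against this age effect. Of the genes that changed with age in WT, 94.8% had a KO effect at 49 days of the opposite sign, with the WT 49-day arrays split so that the age effect and the KO effect shared no array (mean of 20 arrangements, 94.3% to 95.3%). It was 95.9% for genes that rise with age and 94.2% for genes that fall. Across genes, which are not independent replicates, the correlation of the changes was -0.88 and the covariance -2.19. With all WT arrays shared the value was 94.8%, and simulated unchanged KO groups against those arrays gave 49.9% with a covariance of 3.56e-04. Those groups were centred on the mean of the same WT arrays, which fixed that outcome in advance. The simulation therefore cannot show what sharing arrays adds, while the split value of 94.8% shares none. For genes that changed at least 2-fold with age the share was 98.2%. Taken against the age effect within KO arrays it was 86.9%, where unchanged groups gave 46.0%. On single KO arrays it ran from 83.2% on replicate A to 94.7% on replicate B.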

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

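The tests on lower germ-cell share, on whole adult testis RNA and on genes near Nsun2 were chosen after the result was seen; the others were written before. A sample far from the other 5 of its group is named where the gap to its nearest neighbour, divided by the range of the group, exceeded Dixon's 95% critical value. By chance about 1 in 20 groups would. Of 76 pairs of list and group 12 exceeded it, and of 104 pairs of named gene and group 10 did, more than chance would give if they were independent, which they are not, since 1 array accounts for many. Among KO 49-day arrays replicate D lay apart, in the early meiotic list (gap ratio 0.784), the pachytene list (0.703), the chromatoid body list (0.740), RNA cytosine-5 methylation (0.741) and cell division (0.810), where it was at -1.09 against the WT mean and the other 5 between 0.26 and 0.58. Among KO 15-day arrays, replicate D lay apart in the early meiotic list (0.698), the chromatoid body list (0.668), Piwil1 (0.755) and Gpx8 (0.642), replicate E in the endothelial list (0.663) and replicate F in Agtr1a (0.694). WT 49-day replicate D was low in the early meiotic list (0.850), and WT 49-day replicate F was low in Smcp (0.644) and high in Col3a1 (0.702). WT 15-day replicate A lay apart in the p53 list (0.721).

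The KO effect differed between the ages, by the interaction term of the limma fit, for 11050 probes, and by camera for the Sertoli cell list (1.53), the round spermatid list (-1.70) and the elongating spermatid list (-2.43), each at an adjusted p = 0.913 with an estimated correlation. The round spermatid call was also lost among probes above background on all 24 arrays (adjusted p = 0.0684). By gene it differed for Ldhc (3.84), Piwil1 (3.34), Fabp9 (3.12), Kcnh3 (2.95), Klk1b21 (2.90), Car2 (-4.37), Pdzd8 (-4.15), Spem2 (-4.12), Noxred1 (-4.08) and Tppp2 (-4.07), where Ldhc and Fabp9 lie near the top of the scale at 49 days and their sizes are not measured. Of 105 other named genes with a called KO change, 73 also had an interaction that passed. Outside the probes, 10 unnamed control signals were bright. With limma, 3 of them differed between KO and WT at 49 days, by at most 0.27 on the log2 scale, and 0 at 15 days.

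Markers of somatic cells were higher in KO at 49 days, and a lower share of germ cells as the sole cause would raise those of each somatic type alike. Over all tested members, Sertoli markers (14 genes) rose by 1.07 more than peritubular markers (7 genes; adjusted over 10 pairs of lists, exact p = 0.00541 over arrays and permutation p = 0.00476 over genes) and by 1.07 more than endothelial markers (7 genes; 0.00541 and 8.60e-05), but dim genes show too small a rise. Among members above background on all 12 arrays of that age, Sertoli markers exceeded endothelial markers by 1.32 (SD over KO arrays 0.28; adjusted exact p = 0.00361 over arrays, permutation p = 0.00220 over genes, not adjusted) and macrophage markers did by 1.05 (SD 0.28; 0.00361 and 0.0250), but that filter keeps 3 endothelial genes, Egfl7 (-0.19) and Vwf (-0.05), named after their values were seen, and Esam (1.21), and drops Cdh5 (1.15) and Emcn (0.94), which rose. Setting members near background to the Sertoli mean pulls the difference toward 0. Sertoli markers then exceeded peritubular ones by 0.67 and endothelial ones by 0.57 (each adjusted exact p = 0.0216 over arrays and permutation p = 0.259 over genes). Of the 7 peritubular genes 5 rose, among them Acta2 (1.62), Mylk (1.49) and Myh11 (0.96), and only Actg2 (-2.21) fell, which widens the peritubular gaps. Robo4, outside the list, was at 3.23, but it was picked from the largest rises and its other probe did not give the same call. A lower germ-cell share therefore cannot be told apart from unequal changes of the somatic types. Quantile normalization as the sole cause is argued against by a rise of the Sertoli list of 1.49 after scale normalization and 1.10 after cyclic loess, against 1.65. Scale normalization left the median change of the tested probes at 0.21, as quantile normalization did, so it cannot show what a shift common to both adds. Cyclic loess moved that median to -0.12, and the rise was smaller there. A change within somatic cells or in their number stays open and was not tested.

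Transcripts of late spermatids stood out on 2 of the 15-day arrays, KO replicate B (gap ratio 0.872 in the elongating list) and WT replicate A (0.840, and 0.803 in Gsg1, 0.736 in Cabs1 and 0.790 in Smcp), which lie on slide 2. The protamine gene Prm1, which the naming rule does not cover and was chosen after its values were seen, was at 12.53 and 10.20 there and at 7.12 or lower on the other 10 arrays. A small amount of whole adult testis RNA would bring the other abundant adult transcripts too, and 97.7% of 43 adult-abundant genes on WT replicate A and 100% on KO replicate B lay above the median of the other 15-day arrays (32.6% to 81.4% on those), at a median share of 0.0545% and 0.233%, or 0.0482% and 0.135% over a wider set of 210 genes. Such RNA would bring equal shares of elongating and round spermatid genes, but on KO replicate B these were 0.294% and 0.0802% (permutation p = 0.0250; WT replicate A 0.0676% and 0.0921%, p = 0.636) with 5 of 21 genes above background, so whole adult testis RNA may be a source on these arrays but cannot be told apart from late germ cells or their RNA. Carry-over over the whole slide cannot be told apart from none, since its only other 15-day array exceeded the other slides by 0.117, with an SD of 0.107.

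Genes near Nsun2 were among those changed at 15 days: within 50 neighbours on each side, 7 of 39 tested genes changed, against 546 of 11761 on other chromosomes (two-sided Fisher's exact p = 0.00199; 13 of 39 in the 12-array fit, p = 0.0377), and without Erap1 and Fastkd3, whose large changes prompted the test, 5 of 37 (exact p = 0.0277; 11 of 37 in the 12-array fit, p = 0.138). They were Fastkd3 (-2.71), Zfp429 (-1.01), Zfp58 (0.65), Zfp87 (-0.59), Clptm1l (-0.53), Zfp825 (0.81) and Erap1 (2.01), of which all but Erap1 were named after their values were seen. Strain variants carried along with the targeted allele could make the change of such genes unrelated to the loss of the protein, but cannot be told apart from their absence, since the excess without the prompting genes depended on the fit. A local effect of the inserted cassette cannot be told apart from them either: among the next 100 neighbours beyond these on each side, which include Ctsl and Zfp367, 6 of 102 genes changed (exact p = 0.479, and 25 of 102 with exact p = 0.163 in the 12-array fit). Zfp367, named after its values were seen, was at -2.38 at 15 days and -2.66 at 49 days. The tested genes nearer to Nsun2 than Fastkd3, among them Med10 (-0.22), Tent4a (-0.03), Ice1 (-0.10) and Adcy2 (-0.27), did not pass at 15 days. Of the 7 changed genes within 50 neighbours, 5 had the same sign at 49 days. Erap1 was at 7.15 on WT 15-day replicate A (gap ratio 0.926, with 4.90 to 5.07 on the other WT arrays of that age). Ctsl was at 6.83 on WT 49-day replicate B (0.747, with 4.99 to 5.46 on the others). In Fastkd3 these samples lay above the KO arrays of their age, at 9.39 and 7.88 against at most 6.97 and 6.56. In Nsun2 they were at 7.24 and 5.79 against at most 5.29 and 6.07. WT 49-day replicate B was nonetheless the lowest WT array of its age in Fastkd3, with the others between 8.58 and 8.75. Among those WT arrays it was also the lowest in Nsun2 and Zfp367 (9.17) and the highest in Erap1 (5.42), each toward KO. The cause was not tested.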

How the results depend on the processing

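The filter on probes above background on at least 6 arrays, the weights per group, the fit without KO 15-day replicate B and WT 15-day replicate A and the overlap of the ages from fits to 12 arrays were chosen after seeing the data; the other settings were fixed before. Where no cause is given, the cause was not tested. The number of probes called at 15 days rested most on how the spread was estimated. It was 948 with a spread pooled over 24 arrays, 3849 in the 12 arrays of that age, 4302 with array weights and 4478 with weights per group, settings in which the wide spread of the KO 49-day arrays counts less or not at all. Leaving out single arrays gave 468 to 2386 calls, the highest without KO 49-day replicate D, and leaving out KO 15-day replicate B with WT 15-day replicate A gave 403. The number changed at 49 days stayed within 1.5 times of 15697 except where fewer probes were tested. Those above background on all 24 arrays gave 8573 calls, with 6679 for the difference between ages, 9724 for age in WT and 6551 for age in KO; 1 probe per gene gave 8964, 6568, 10119 and 7102. Array weights raised the difference between ages to 16851. Leaving out single arrays gave 14802 to 16465 calls at 49 days, 9720 to 12973 for the difference, 18097 to 18938 for age in WT and 12111 to 15183 for age in KO.

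Of the 57 list tests, 11 passed with camera at the preset correlation, 0 with an estimated correlation and 21 with fry, and 10 to 12 when an array was left out. The share of age-regulated genes with an opposite KO effect was 86.9% when the age effect was taken in KO, and 94.0% to 95.5% when an array was left out. Nsun2 lay between -1.62 and -1.34 at 15 days and between -1.31 and -1.07 at 49 days when an array was left out; it was not among the probes above background on all 24 arrays, so that setting gives no value for it. Without background correction it was -0.45 and -0.34.

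Of 133 calls of named genes over the contrasts, 10 were lost after cyclic loess, 8 with weights per group, 6 without background correction, 6 on the authors' values, 5 with no filter and 4 after scale normalization. At 15 days, 5 of 29 were lost without background correction and 2 after cyclic loess.

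Apart from the values within single slides, which were not tested and are given below, some values changed sign. None of these passed in either setting. Many were near 0. The differences between ages were larger, at up to 0.43 after quantile normalization, where cyclic loess moved the median of the tested probes from 0.23 to -0.10. Values outside those differences also moved away from 0, namely cell division (-0.34) and epididymis (-0.21) at 49 days and the elongating list at 15 days (-0.30). After scale normalization the undifferentiated spermatogonia list at 15 days was 0.032 and cell division 0.011. After cyclic loess, Cst11 at 15 days was -0.018, the elongating spermatid list -0.042, and at 49 days the epididymis list was -0.21 and cell division -0.34. The differences between ages were then -0.062 for peritubular myoid, -0.24 for early meiotic prophase, -0.26 for pachytene, -0.28 for the chromatoid body, -0.37 for RNA cytosine-5 methylation, -0.15 for cholesterol synthesis and -0.30 for cell division. The epididymis list at 49 days was -0.043 with no filter and -0.070 with the looser filter on probes above background on at least 3 arrays. RNA cytosine-5 methylation at 49 days was 0.074 among probes above background on all 24 arrays and 0.022 with array weights, which put undifferentiated spermatogonia at 15 days at 0.019. With the slide as a block Cst11 was -0.052, and with replicate and slide blocks it was -0.042 and the elongating list -3.76e-05. Leaving out arrays at 15 days moved Cst11 between -0.087 and 0.13, Hba-a1 between -0.017 and 0.24, undifferentiated spermatogonia between -0.080 and 0.050, cell division between -0.067 and 0.0098 and the elongating list between -0.30 and 0.18, the lowest without KO replicate B. At 49 days the epididymis list ran from -0.039 to 0.12 and RNA cytosine-5 methylation from -0.11 to 0.032, and both changed sign without KO replicate D.

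Within single slides, each with 1 or 2 arrays per group, 4 called values had the other sign: Erap1 on slide 2 (-0.29), macrophages on slide 3 at 15 days (-0.38), and Sall4 (-0.28) and Mcm5 (-0.10) on slide 4 at 49 days. The slide term passed for 6 probes and the replicate letter for 0 in limma, with 1133 and 705 at an unadjusted p under 0.05. Correlations between arrays of the same letter lay between -0.21 and 0.39, so the letters were not used as pairs. Signal over background limits the dim genes: the offset and the background level compress their folds, and a gene above background on 0 arrays of a group has only a bound.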

Other observations

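The tests in this part were written before their results were seen. X-linked genes were higher in KO at 49 days: the median change was 1.02 over 457 X-linked genes and 0.28 over 11652 autosomal genes (camera adjusted p = 4.36e-05 over 5 contrasts; p = 0.202 with an estimated correlation). At 15 days 20 X-linked genes rose and 0 fell by limma (medians 0.22 and -0.00; camera p = 2.01e-10 before adjustment, p = 0.0648 with an estimated correlation). Since X-linked genes also fall with age in WT, the rise at 49 days could follow from the general loss of late germ cell transcripts. After the trend of the KO change on the WT age change was removed, with the WT 49-day arrays split, the difference from autosomes went from 0.738 to 0.179 (0.0962 to 0.260 over 20 arrangements), so most of it followed that trend. The remainder sits close to the bound set for this reading and its cause was not tested.

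Lower meiotic transcripts in KO at 15 days may mean that these testes lie earlier on the normal course from 15 to 49 days. Of the genes that change with age in WT, 61.7% had a KO change at 15 days of the opposite sign, with the WT 15-day arrays split (57.8% to 65.2% over 20 arrangements), which lies just above the bound set beforehand and, in some arrangements, below it. The values fit such a shift narrowly, and a loss of germ cells at the pachytene stage, which was not tested, stays open.

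Other splits of the arrays into groups of the same sizes were drawn, 100 per comparison with the real one included. In 1 of 100, the real one, the count was as large in each of the 5 comparisons. That is the smallest share that 100 splits can give, so it bounds chance without excluding it. The splits also treat the arrays as independent samples, which the labels do not state. At 15 days 948 probes passed and at most 2 in another split. At 49 days it was 15697 against 14746, for the difference between ages 11050 against 10447, for age in WT 18413 against 14675 and for age in KO 13080 against 11633. The highest other splits at 49 days, for the difference and for age in WT differ from the real one, or its mirror image, by an exchange of 1 array of each of a pair of groups, and that for age in KO exchanges KO 15-day replicate F and KO 49-day replicate D.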
